A study of Mus musculus with 6 samples.

How the data were processed

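Messenger RNA was measured by RNA sequencing in 6 libraries of mouse bone marrow cells that had been cultured for 4 days with GM-CSF, 3 without and 3 with added potassium chloride (KCl). Groups and replicate numbers (1, 2 and 4 in each group) came from the sample titles and treatment labels. The labels do not say whether replicates came from separate mice or separate cultures, so p-values measure the spread between these samples, which may be technical.

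Per the labels' protocols, total RNA was extracted with Trizol and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.3.3b and edgeR were used with the mouse build mm10. The counting program and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The authors deposited a table of 19162 genes with a whole-number read count and an FPKM value per library. For genes with at least 10 counts in the libraries compared, the gene length implied by the deposited FPKM, the count and the library total was the same in every library to a relative deviation of 7.6e-05, and FPKM was not used in any test. Symbols were used as the table gives them, 44 entries share a symbol with another and 24 symbols read as calendar dates. Of the 19162 gene IDs, 19049 matched GENCODE M21, from which coordinates on mm10 (GRCm38) were taken.

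The deposited counts of control 4 and KCl 4 were not independent of the other 4 libraries. For each of 8231 genes with a mean count of at least 300, the mean CPM (counts scaled to library size) of these 2 libraries was divided by that of the other 4. The log2 ratio had an SD over genes of 0.011, where counting noise alone gives 0.044 and the 14 other pairs of libraries gave 0.123 to 0.262. No source used here records a step that would do this, and the counts were tested as deposited. P-values that use all 6 libraries may therefore be too small. In simulated counts of 13525 genes with no group effect and a batch SD of 0.5 on the log2 scale, the test called 0 genes before a batch adjustment by ComBat-seq (sva 3.50.0) with the group in its model and 142 after it, but 0 after an adjustment without the group. Results without both of these libraries are given beside the counts of changed genes, and were planned before the data were examined.

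Library totals were 20789328, 21694831 and 14118724 counts for control 1, 2 and 4, and 18933948, 17814232 and 17935912 for KCl 1, 2 and 4. Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13326, and libraries were scaled by TMM. KCl was compared with control in the robust quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 over all tested genes. Log2 fold changes are KCl minus control and carry their standard error (SE). CPM values are TMM-scaled.

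A total of 26 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26 lists. They covered suppressive effectors of myeloid-derived suppressor cells, immature granulocytes, neutrophils, monocytes, macrophages, dendritic cells, eosinophils with basophils and mast cells, lymphocytes, erythroid cells and megakaryocytes, stromal and endothelial cells, potassium channels and cation transporters, the hyperosmotic response, calcium-dependent early genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, lipid metabolism, type I interferon, inflammatory cytokines, alternative macrophage activation, cell cycle, unfolded protein and integrated stress, NRF2, hypoxia, lysosome and autophagy, and p53 with apoptosis. For each list, members were also counted after adjustment over the list alone. Camera with an estimated correlation, and fry, which asks whether a set's own genes move one way, were alternatives.

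Genes to name were chosen by a rule fixed before the data were examined. It took the 10 that rose and the 10 that fell most among named genes past the threshold with a mean CPM of at least 10 in the higher group and no overlap between groups, up to 4 members of each list with the smallest p, and always Arg1, Nos2, S100a8, S100a9, Cd274, Ly6g, Ly6c2, Kcnj2 and Nfat5. The rule gave 125 tested genes. Other list members given as examples, and the genes in the closing observations, were chosen after their values were seen. Values of some single genes are not reported here.

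Alternatives were RLE, upper-quartile and library-size scaling, no filter, a mean CPM of at least 5, the replicate number as a block, each library left out, replicate 4 left out, DESeq2 1.42.0 and limma-voom. A term for replicate 4 as a batch and a term for another split of the samples were added after the data were seen.

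The test was checked on simulated counts for 13144 genes in 3 and 3 libraries, with 50 genes changed at each fold. It recovered 42% of genes changed 1.5-fold, 72% at 2-fold, 92% at 4-fold and 94% at 8-fold, and 11 of its 161 calls (6.8%) were false. The simulated libraries were independent, unlike the deposited ones, and few genes were changed, so these shares may not hold for the data. In a like check of the list test on 13151 genes, the raised list was called and 0 others were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.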

Results

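Gene expression was compared between bone marrow cells of C57BL/6J mice grown for 4 days with 40 ng/mL GM-CSF, a cytokine that drives myeloid cells to grow and mature, with or without 34.7 mM of extra KCl. The series describes the cells as bone marrow-derived myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells, under high potassium. Each group had 3 libraries, with totals from 14118724 to 21694831 counts. The first principal component of log2 CPM held 53.3% of the variance and separated the groups, from -33.9 to -21.4 in control and from 22.5 to 34.0 in KCl. KCl also raises osmolality, and a control with another salt or solute was not analysed here. Mitochondrial genes took 3.89% to 4.80% of counts in control and 3.26% to 3.61% in KCl.

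The comparison asked which genes respond to high potassium. Csn2, which encodes the milk protein beta-casein, rose most among the genes singled out, with a log2 fold change of 6.81 ± 0.48 (SE, n = 3 per group) from counts of 1, 3 and 5 in control to 247, 421 and 332 in KCl. Its fold change was 7.55 ± 0.61 without replicate 4 and 7.54 without control 4 alone. Slc6a12, the betaine and GABA transporter that brings in osmolytes, rose by 2.46 ± 0.13, from 19.3 ± 3.19 to 105 ± 8.64 CPM (mean ± SD). Slco4a1, an organic anion transporter, rose from 77.8 ± 11.1 to 371 ± 18.7 CPM, and Kcnj10, an inward-rectifier potassium channel, rose from 2.12 ± 0.367 to 11.9 ± 0.916 CPM. The eosinophil-associated ribonuclease gene Ear1 fell by 4.05 ± 0.09 on the log2 scale, from 101 ± 6.67 to 6.08 ± 0.531 CPM. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00207 for Csn2, 0.00154 for Slc6a12, Slco4a1 and Kcnj10, and 6.8e-05 for Ear1. All 3 KCl libraries lay beyond all 3 control libraries for each, but the naming rule required this. The same held for 38.5% of all tested genes.

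With all 6 libraries, 3057 of 13326 genes passed, 1655 higher and 1402 lower in KCl, and 549 changed at least 2-fold (291 higher, 258 lower). The balance of directions turned with upper-quartile scaling, which called 1422 higher and 1735 lower. These counts use control 4 and KCl 4, whose mean CPM tracked that of the other 4 libraries more closely than counting noise allows. The SD was 0.011 on the log2 scale over 8231 genes, against 0.044 for counting noise. The libraries were therefore not independent, and the p-values may be too small. Without control 4 and KCl 4, 62 genes passed (45 higher, 17 lower), of which 52 also passed with all 6, and 51 changed at least 2-fold. Fewer libraries account for part of this drop, and no other pair was left out for comparison. All 3057 genes kept their sign, and log2 fold changes correlated at 0.941 across genes, though both fits share 4 libraries. The count of changed genes was 1439 without control 4 alone and 1505 without KCl 4 alone. It was 1573 with replicate 4 as a batch term, a fit added after the data were seen.

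**Figure D1:**
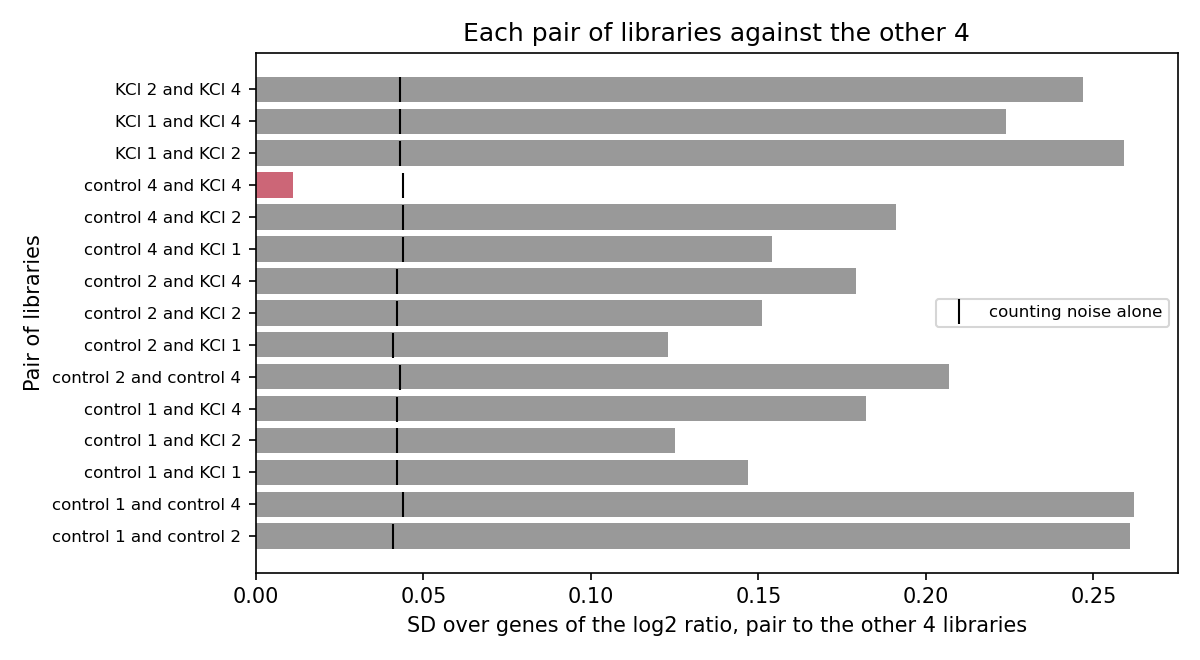
The SD over 8231 genes of the log2 ratio between the mean CPM of a pair of libraries and that of the other 4 is plotted for all 15 pairs, with the SD that counting noise alone gives as a black tick. The pair of control 4 and KCl 4 lies at 0.011, below its tick at 0.044, and the 14 other pairs lie between 0.123 and 0.262.

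Of the genes named by the fixed rule, 109 of 125 passed with all 6 libraries, and 14 of them also passed without replicate 4. The 8 that rose in both fits were Csn2, Slco4a1, Slc6a12, Kcnj10, Pgr (the progesterone receptor, 2.26 ± 0.13), Plxdc1 (2.23 ± 0.17), C1qc (a chain of complement C1q, from 5.74 to 16.2 CPM) and Kit (the stem cell factor receptor, 0.93 ± 0.06). The 6 that fell in both were Ear1, Ear2 (-2.33 ± 0.17), Ear6 (-1.68 ± 0.09), Ccl17 (a chemokine that attracts T cells through CCR4, -1.58 ± 0.09), Prg2 (eosinophil major basic protein, -1.24 ± 0.08) and Asns (asparagine synthetase, -1.05 ± 0.06). Every other gene said to have risen or fallen passed with all 6 libraries and not without replicate 4, unless stated. Ear1, Ear2 and Ear6 are near copies of one another, and reads between them may have been split by the counting.

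**Figure D2:**
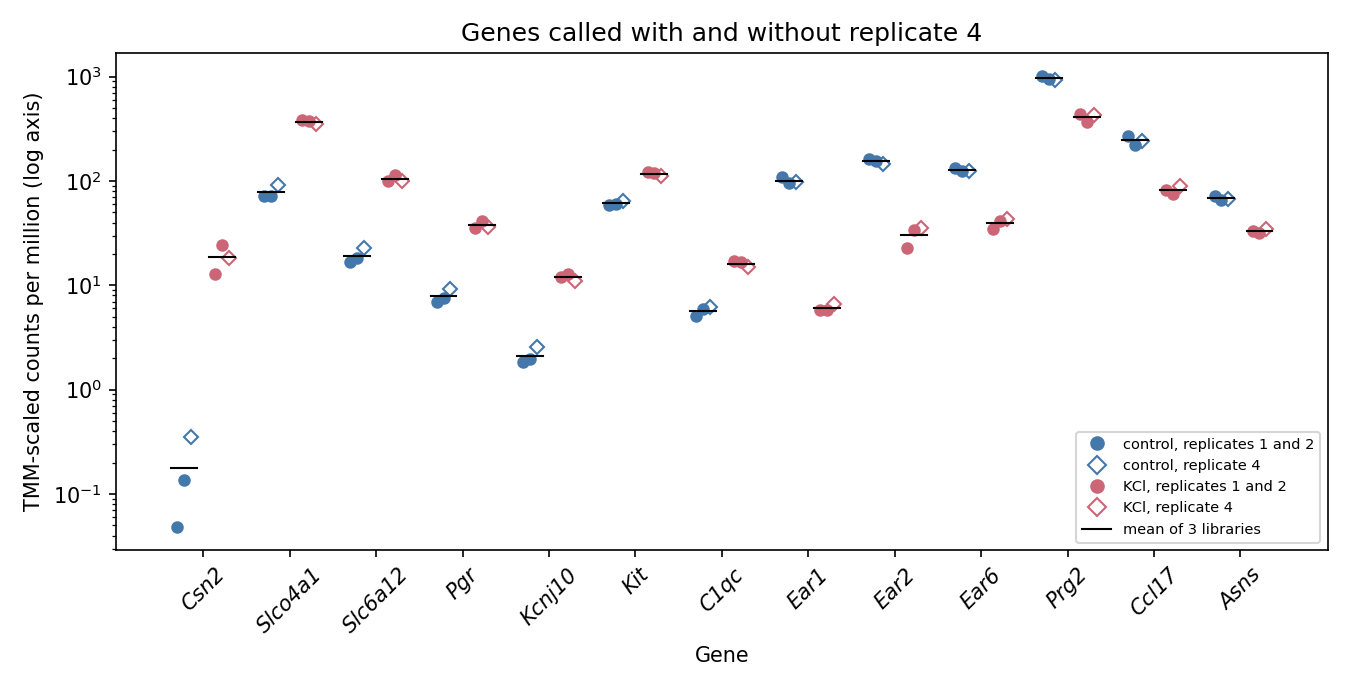
TMM-scaled CPM on a log axis is plotted per library for 13 of the 14 genes that passed both with and without replicate 4, with circles for replicates 1 and 2, open diamonds for replicate 4 and a black line for the mean of 3. Ear1 fell from 101 to 6.08 CPM and Slco4a1 rose from 77.8 to 371 CPM.

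Csn2 (ENSMUSG00000063157) lies on chromosome 5 of mm10 from 87692624 to 87699630 on the minus strand. Slc6a12 (ENSMUSG00000030109) lies on chromosome 6 from 121343076 to 121365775, Slco4a1 (ENSMUSG00000038963) on chromosome 2 from 180456245 to 180474867 and Kcnj10 (ENSMUSG00000044708) on chromosome 1 from 172341210 to 172374085, all on the plus strand. Ear1 (ENSMUSG00000072601) lies on chromosome 14 from 43818765 to 43875517 on the minus strand, and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484 on the minus strand. GENCODE M21 lists all of these as protein-coding, and the values are for the whole gene.

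Among the largest rises, Mcoln3, an endolysosomal cation channel, rose by 3.11 ± 0.27 on the log2 scale, Aldh1a3, a retinaldehyde dehydrogenase, by 2.80 ± 0.25, and the acute-phase gene Saa3 by 2.36 ± 0.21. Ces1d rose by 2.69 ± 0.62 (3.64 without control 1), but its adjusted p in the quasi-likelihood test was 0.0803 without control 4, 0.0752 without KCl 1 and 0.0693 without KCl 4. The largest falls included the dynein gene Dnah2 (-2.58 ± 0.21), the MHC class II gene H2-Eb2 (-2.49 ± 0.36), Dpysl5 (-2.32 ± 0.31), the stefin-family gene BC100530 (-2.04 ± 0.19) and Serpinb6b (-1.95 ± 0.22). H2-Eb2, BC100530 and Serpinb6b have close relatives and are uncertain in the same way as the Ear genes. Mrvi1 (-1.98 ± 0.48) and mt-Atp6 (-1.84 ± 0.45) also fell, but Mrvi1 missed the threshold when control 1, control 4 or any 1 KCl library was left out (edgeR adjusted p from 0.0704 to 0.0974), and mt-Atp6 when control 1, control 4, KCl 1 or KCl 4 was (0.059 to 0.0971). The mt-Atp6 values varied widely, at 6725, 3006 and 5469 CPM in control and 748, 2134 and 1351 in KCl. Other mitochondrial genes moved far less: mt-Atp8 stood at 1381, 1239 and 1309 CPM in control and at 1073, 1069 and 1058 in KCl.

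Genes of the hyperosmotic response, driven by the transcription factor NFAT5, stood above other genes (camera adjusted p = 9.65e-05, 16 members tested). This became adjusted p = 0.341 with an estimated correlation. Members that rose numbered 7, members that fell 0, and 9 did not pass, with the same counts when adjusted over the list alone. Besides Slc6a12, the osmolyte and amino acid carriers Slc5a3 (1.24 ± 0.11), Slc38a2 (0.69 ± 0.07) and Slc6a6 (0.59 ± 0.06) rose, as did Nfat5 itself (0.79 ± 0.10). The heat shock genes Hspa1a (0.00 ± 0.17) and Hsph1 (-0.08 ± 0.09) and the aldose reductase gene Akr1b3 (-0.11 ± 0.16) did not pass.

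Potassium channel and cation transporter genes were also higher as a list (camera adjusted p = 0.0142, and adjusted p = 0.324 with an estimated correlation). Of 23 tested, 9 rose, 3 fell and 11 did not pass, against 11 and 3 adjusted over the list alone. After Kcnj10, the inward rectifier Kcnj2 rose by 0.74 ± 0.11, the sodium pump subunit Atp1b3 by 0.55 ± 0.07 and the potassium-chloride cotransporter Slc12a7 by 0.54 ± 0.08. The beta subunit Kcnab2 (-0.45 ± 0.12), the sodium-potassium-chloride cotransporter Slc12a2 (-0.37 ± 0.09) and the kinase gene Wnk1 (-0.27 ± 0.06) fell, but each missed the threshold without control 1, control 4, KCl 2 or KCl 4 (edgeR adjusted p from 0.0518 to 0.129), Kcnab2 also without control 2 (0.115), and Slc12a2 also without control 2 (0.0575) or KCl 1 (0.0716). Calcium-dependent early genes were not called (camera adjusted p = 0.45), with 4 of 20 rising and 1 falling, or 4 and 3 adjusted over the list alone. Ier3 (0.99 ± 0.11) and Dusp1 (0.50 ± 0.06) rose and Egr1 fell by 0.49 ± 0.07.

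Lysosome and autophagy genes gave the smallest p of the 26 lists (camera adjusted p = 1.55e-07, and adjusted p = 0.531 with an estimated correlation). Of 27 tested, 17 rose, 0 fell and 10 did not pass, and 21 rose when adjusted over the list alone. The cathepsins Ctsl (0.69 ± 0.10), Ctss (0.61 ± 0.08) and Ctsb (0.60 ± 0.09) and the membrane protein gene Lamp1 (0.48 ± 0.07) were among them. Targets of NRF2, which controls the defence against oxidants, were higher too (camera adjusted p = 3.4e-05, and adjusted p = 0.531 with an estimated correlation). Of 19, 12 rose, 1 fell and 6 did not pass, or 13 and 1 adjusted over the list alone, with rises of Osgin1 (1.41 ± 0.17), Me1 (1.16 ± 0.14), Gclm (0.57 ± 0.11) and Gclc (0.40 ± 0.06) and a fall of the metallothionein gene Mt1 (-0.31 ± 0.07). Mt1 missed the threshold without any 1 library but control 1 (edgeR adjusted p from 0.0565 to 0.0971).

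**Figure D3:**
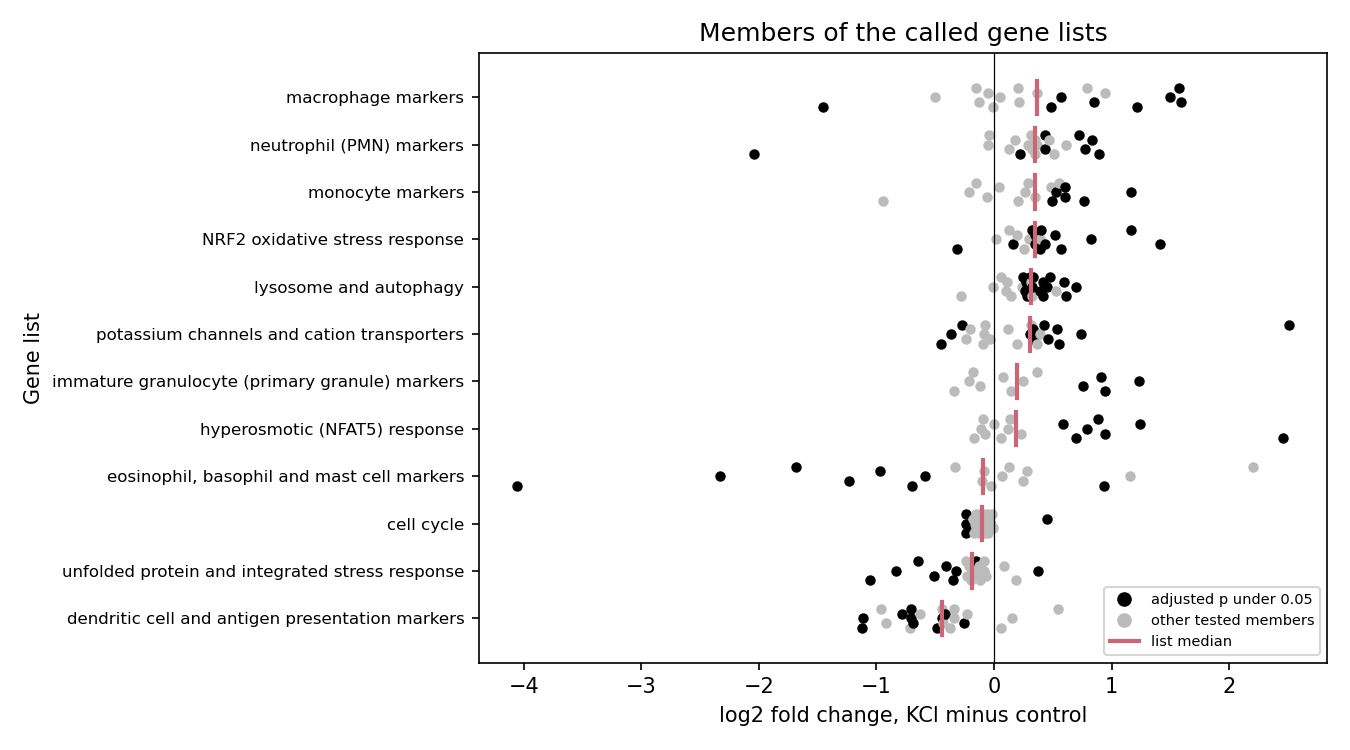
The log2 fold change (KCl minus control) of each tested member is plotted for the 12 lists called by camera, in black for members past the threshold with all 6 libraries, grey for others, with a red bar at the list median. The median was 0.31 for lysosome and autophagy and -0.45 for dendritic cell genes.

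Dendritic cell and antigen presentation genes were lower (camera adjusted p = 1.76e-06, and adjusted p = 0.531 with an estimated correlation). Of 23 tested, 0 rose, 10 fell and 13 did not pass, and 17 fell when adjusted over the list alone. The integrin Itgax (CD11c) fell by 0.70 ± 0.05, the MHC class II gene H2-Eb1 by 0.71 ± 0.12 and the costimulatory gene Cd80 by 0.78 ± 0.13 on the log2 scale. Relative to the mean of the 6 libraries, the list's median stood at 0.36, 0.05 and 0.34 in control 1, 2 and 4 and at -0.05, -0.48 and -0.32 in KCl 1, 2 and 4.

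Monocyte genes (camera adjusted p = 0.00618, and adjusted p = 0.531 with an estimated correlation) and macrophage genes (0.00627, and adjusted p = 0.624 with an estimated correlation) were higher as lists. Of 17 monocyte genes, 6 rose, 0 fell and 11 did not pass, or 7 and 1 adjusted over the list alone. The inflammatory monocyte marker Ly6c2 (0.60 ± 0.10), the lipopolysaccharide receptor gene Cd14 (0.77 ± 0.10) and Ms4a6c (1.16 ± 0.13) rose. Of 19 macrophage genes, 7 rose, 1 fell and 11 did not pass, or 9 and 1 adjusted over the list alone. Besides C1qc, the cathepsin gene Ctsk rose by 1.57 ± 0.17 and Cd63 by 0.57 ± 0.07, while Spp1 (osteopontin) fell by 1.46 ± 0.13 on the log2 scale.

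Neutrophil genes were higher (camera adjusted p = 0.00618, and adjusted p = 0.699 with an estimated correlation), with 7 of 21 rising, 1 falling and 13 not passing, or 9 and 1 adjusted over the list alone. Cd177 (0.89 ± 0.13), the G-CSF receptor gene Csf3r (0.77 ± 0.11) and Il1f9 (0.72 ± 0.12) rose, and BC100530 fell. The abundant alarmin genes S100a8 (-0.05 ± 0.22) and S100a9 (0.35 ± 0.14) and the granulocyte surface marker Ly6g (0.32 ± 0.41) did not pass. The list median did not separate the groups, since it stood at 0.14 in control 4 and at -0.16 in KCl 4, and camera's adjusted p was 0.0643 without KCl 2. Immature granulocyte genes were called with all 6 libraries (camera adjusted p = 0.0282, and adjusted p = 0.531 with an estimated correlation), but the adjusted p was 0.0684 without KCl 4 and 0.483 without replicate 4. Of 12, 4 rose and 0 fell, also when adjusted over the list alone, namely Nkg7 (1.23 ± 0.12), Fcnb (0.94 ± 0.15), the elastase gene Elane (0.91 ± 0.14) and Hp (0.76 ± 0.10), and 8 did not pass.

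Eosinophil, basophil and mast cell genes were lower as a list (camera adjusted p = 0.00618, and adjusted p = 0.324 with an estimated correlation), with 1 of 18 rising, 7 falling and 10 not passing, or 2 and 7 adjusted over the list alone. The list median was only -0.09, and 0.01 with the term for the split of the samples. The 7 that fell were Ear1, Ear2, Ear6, Prg2, the eosinophil peroxidase gene Epx (-0.97 ± 0.09), the basophil protease gene Mcpt8 (-0.69 ± 0.08) and Gata1 (-0.59 ± 0.17), and Kit rose. Gata1 missed the threshold without any 1 library but control 2 (edgeR adjusted p from 0.0529 to 0.141). Siglecf (0.13 ± 0.15), Ccr3 (0.28 ± 0.33) and Il5ra (-0.33 ± 0.24), surface receptors found on eosinophils, did not pass. Neither did the mast cell protease gene Cpa3 (0.07 ± 0.14). Ms4a2 (1.15 ± 0.42) and the scarce Tpsb2 (2.20 ± 0.72, from 0.17 to 0.84 CPM) were higher in KCl but did not pass either. The fall was therefore not shared by the mast cell members of the list.

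MDSC suppressive effector genes were not called with all 6 libraries (camera adjusted p = 0.283), and were called higher without replicate 4 (0.0165), where 0 single members passed. Relative to the mean of the 6 libraries, the list median was reversed in replicate 4, at 0.07 in control 4 and -0.08 in KCl 4. It stood at -0.18 and -0.13 in control 1 and 2 and at 0.07 and 0.16 in KCl 1 and 2. With all 6 libraries this list had an adjusted p = 0.75 with an estimated correlation. Of 21 tested, 4 rose, 3 fell and 14 did not pass, with the same counts adjusted over the list alone. The cyclooxygenase gene Ptgs2 (from 1.93 to 5.46 CPM), the NADPH oxidase genes Cybb (0.49 ± 0.10) and Ncf1 (0.38 ± 0.06) and Cd84 (0.36 ± 0.08) rose. Arg1, the arginase of suppressive myeloid cells, was scarce, at counts of 20, 129 and 60 in control and 3, 6 and 6 in KCl, and fell by 3.70 ± 0.81 on the log2 scale. Its adjusted p in the quasi-likelihood test was 0.0225, against 0.0568 without control 4 and 0.0672 to 0.079 without any 1 KCl library. Cybb likewise missed the threshold without control 1, control 4 or KCl 4 (0.0553 to 0.0627), and Cd84 without control 4 (0.0531). Cd274, which encodes PD-L1, stood at 224 CPM in both groups (log2 fold change 0.00 ± 0.05). Nos2 was too low to test, with counts of 3, 3 and 19 in control and 21, 8 and 3 in KCl.

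Unfolded protein and integrated stress genes were lower (camera adjusted p = 0.00102, and adjusted p = 0.324 with an estimated correlation), with 1 of 22 rising, 8 falling and 13 not passing, or 1 and 9 adjusted over the list alone. The genes that fell included Asns and the serine and folate pathway genes Psat1 (-0.51 ± 0.04) and Mthfd2 (-0.41 ± 0.04), which ATF4 controls. Xbp1, a transcription factor of the unfolded protein response, rose by 0.38 ± 0.05. Cell cycle genes were called lower (camera adjusted p = 0.0434, and adjusted p = 0.75 with an estimated correlation). They were not called without control 1, control 2, KCl 1 or KCl 2 (0.108 to 0.222), or with replicate 4 as a batch term (0.0713). Nor were they with a term for the split of control 4, KCl 1 and KCl 2 from the rest (0.236), also added after the data were seen, where the list median moved from -0.11 to -0.01. They were called without control 4 (0.00202), without KCl 4 (0.00335) and without both (1.21e-05, median -0.24). Relative to the mean of the 6 libraries, the list median was reversed in that pair, at -0.10 in control 4 and 0.08 in KCl 4. Of 30, 4 fell, 1 rose and 25 did not pass, or 3 and 1 adjusted over the list alone. The transcription factor gene E2f1 rose by 0.45 ± 0.05. The kinetochore motor gene Cenpe fell by 0.24 ± 0.04 on the log2 scale, but missed the threshold without control 4 (edgeR adjusted p = 0.0546) or KCl 4 (0.0587).

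The remaining lists were not called by camera. Of 20 p53 and apoptosis genes, 3 rose and 7 fell (adjusted p = 0.259, the same counts adjusted over the list alone), with falls of Bcl2a1b (-0.62 ± 0.09) and Ccng1 (-0.37 ± 0.06). Of 24 inflammatory genes, 4 rose and 2 fell (adjusted p = 0.45; 6 and 5 adjusted over the list alone), with a rise of the neutrophil chemokine gene Cxcl3 (1.54 ± 0.24) and falls of Il12b (-2.24 ± 0.41; edgeR adjusted p = 0.0531 without KCl 4) and Relb (-0.59 ± 0.11). Of 18 alternative macrophage genes, 2 rose and 4 fell (adjusted p = 0.283; 3 and 4 adjusted over the list alone). Ccl17, Arg1, Flt1 (-1.05 ± 0.09) and the lectin gene Mgl2 (-0.75 ± 0.11) fell, and Cd163 rose from counts of 1, 0 and 2 to 22, 27 and 23. That list had a median of -0.16, a mean of 0.03 and a test direction of down.

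Among metabolic lists, glycolysis had 3 of 20 rising and 1 falling, also adjusted over the list alone (camera adjusted p = 0.838), with Hk3 up by 0.55 ± 0.08. Lipid metabolism had 2 of 25 rising and 3 falling, also adjusted over the list alone (0.269), with falls of the nuclear receptor gene Pparg (-0.64 ± 0.07) and the acetyl-CoA carboxylase gene Acaca (-0.50 ± 0.08). Oxidative phosphorylation had 2 of 35 rising and 0 falling, and 0 of either adjusted over the list alone (0.968). It was called lower without replicate 4 (adjusted p = 0.00731), where 0 of 35 members passed, its median was 0.02 with the term for the split of the samples, and with all 6 libraries it had an adjusted p = 0.998 with an estimated correlation. Relative to the mean of the 6 libraries, its median was reversed in replicate 4, at -0.16 in control 4 and 0.15 in KCl 4. It stood at 0.08 in both control 1 and 2 and at -0.09 and -0.04 in KCl 1 and 2. Cholesterol synthesis had 1 of 24 rising and 2 falling, or 1 and 1 adjusted over the list alone (0.297), with a median of -0.06, a mean of 0.04 and a test direction of down, and was called lower without KCl 1 (0.0344), against adjusted p = 0.804 with an estimated correlation and all 6 libraries. The farnesyl diphosphate synthase gene Fdps fell by 0.27 ± 0.05, with an edgeR adjusted p of 0.0576 without control 4 and 0.0625 without KCl 4. Hypoxia had 0 of 18 rising and 3 falling, also adjusted over the list alone (0.45), with a median of 0.11, a mean of -0.03 and a test direction of down. The oxidoreductase gene Ero1l fell by 0.76 ± 0.15, with an edgeR adjusted p of 0.0527 without control 4 and 0.0565 without KCl 4.

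Type I interferon genes had 0 of 30 rising and 2 falling, and 0 of either adjusted over the list alone (camera adjusted p = 0.45). Lymphocyte genes had 2 of 8 rising and 1 falling, also adjusted over the list alone (0.298), with Ighm up by 0.87 ± 0.09 and the interleukin-7 receptor gene Il7r down (-1.22 ± 0.21). Erythroid and megakaryocyte genes had 0 of 9 rising or falling (0.993). Stromal and endothelial genes had 3 of 14 rising and 0 falling, also adjusted over the list alone (0.0974), with rises of Acta2 (1.35 ± 0.17) and Cp (1.28 ± 0.11). That list was called higher without control 4 (0.0185), without KCl 4 (0.0212) and without both (0.00522), against adjusted p = 0.682 with an estimated correlation and all 6 libraries. Relative to the mean of the 6 libraries, its median was reversed in replicate 4, at 0.16 in control 4 and -0.16 in KCl 4. It stood at -0.28 and -0.26 in control 1 and 2 and at 0.36 and 0.48 in KCl 1 and 2. Of the 12 lists called with all 6 libraries, 11 were also called without replicate 4 and 0 with an estimated correlation, where the smallest adjusted p was 0.324 and 3 lists had an unadjusted p under 0.05. By fry, the lists of dendritic cells (adjusted p = 0.0608), macrophages (0.0503), neutrophils (0.202) and cell cycle (0.34) were not called, while those of calcium-dependent early genes (0.00104) and lipid metabolism (0.00745), which camera did not call, were.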

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

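The terms for replicate 4 as a batch and for the other split of the samples were chosen only after the results were seen. The count of changed genes stayed within 1.5 times its value of 3057 under RLE (2998), upper-quartile (3157) and library-size scaling (3094), no filter (2786), a mean CPM of at least 5 (2553), DESeq2 (2615), limma-voom (3002) and the split term (2130). It fell to 1573 with the batch term and to 62 without replicate 4, and ranged from 1439 to 2851 with 1 library left out, lowest without control 4 (1439) and without KCl 4 (1505). Fewer libraries account for part of these losses, and how much came from the relation of replicate 4 to the other libraries was not tested. The count of genes changed at least 2-fold (549) ranged from 399 to 674 with 1 library left out, and was 209 at a mean CPM of at least 5, where fewer genes were tested (10481), 423 with the batch term and 51 without replicate 4.

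Camera called 10 to 13 lists with 1 library left out, 14 without replicate 4, 11 with the batch term and 0 with an estimated correlation. That correlation was below the preset 0.01 for the potassium (-0.026), eosinophil (-0.015) and unfolded protein (-0.008) lists. This argues against a stronger correlation between genes as the cause of their loss. For the other lists among the 12 the estimate was higher, from 0.077 to 0.704. The cause was not tested further. Fry called 10 lists by direction, 8 of them among the 12. Apart from fry and the estimated correlation, 9 of the 12 lists passed under every setting run, and the adjusted p of the 12 ranged up to 0.483, for immature granulocytes without replicate 4.

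With the replicate number as a replicate block, 1678 genes, 432 genes changed at least 2-fold and 11 lists were called, and the cell cycle list was lost (adjusted p = 0.0766). Same-numbered libraries deviated from their group means with correlations of 0.02, -0.06 and -0.75, and no library correlated best with the library of its own number. These values cannot show whether the numbers pair the samples. The mean CPM of control 4 and KCl 4 tracked that of the other libraries, which pushes the deviations of this pair in opposite directions.

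Of the 109 named genes that passed, 95 no longer did without replicate 4, 22 with the batch term, 16 with the block, 14 with the split term, 25 without control 4, 24 without KCl 4 and at most 14 without any other library. Between 0 and 3 were lost under each other scaling, filter or tool. Sign changes under these scalings, filters and tools numbered 0. In simulated data, 42% of genes changed 1.5-fold were recovered. Those libraries were independent and few genes were changed (50 at each fold), so this share may not hold for the data. The median log2 fold change of called genes was 0.515 for rises and -0.436 for falls.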

Other observations

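Tests chosen only after the result was seen were the counts of splits for changed genes and for genes changed at least 2-fold, the exchanged labels, the comparison of control 4 and KCl 4 with the other libraries, and the 3 tests on eosinophil genes. Also set after values were seen were the bound for exchanged labels, lowered from a higher one that the share did not reach, the rule that the neutrophil value must pass its bound by more than its spread, the reading of the STAT5 test as open, and the adjustment of simulated libraries with the group in its model.

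Genes outside the lists passed edgeR's quasi-likelihood test both with all 6 libraries and without replicate 4, and those given here were singled out after their values were seen. Fxyd2, the gamma subunit of the sodium pump, had counts of 0, 1 and 6 in control and 63, 68 and 52 in KCl, where it stayed scarce (2.88 to 3.97 CPM). Cftr, a chloride channel, went from 1, 1 and 0 to 43, 46 and 45, and Slc6a20a, an imino acid carrier, from 2, 2 and 0 to 42, 34 and 40. Sdc1 (syndecan-1) rose by 1.85 ± 0.12 on the log2 scale (SE, n = 3 per group), Plxnb2 (plexin B2) by 1.54 ± 0.08, Tns1 (tensin 1) by 1.47 ± 0.08 and the nuclear receptor gene Rora by 2.04 ± 0.12. Stc2 (stanniocalcin 2) fell by 2.79 ± 0.15, Plet1 by 1.36 ± 0.06 and Prg3, a relative of Prg2, by 1.20 ± 0.08.

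Without replicate 4, 10 genes passed that did not with all 6 libraries. Nek7, a kinase needed for the NLRP3 inflammasome, stood at 33.1 and 34.2 CPM in control 1 and 2 and at 134 and 138 in KCl 1 and 2, but at 128 in control 4 and 40.7 in KCl 4. The glutathione peroxidase gene Gpx1 stood at 220 and 244 against 642 and 680 CPM, with 616 in control 4 and 265 in KCl 4. The chloride transporter gene Clcn5 did likewise (18.4 and 18.5 against 57.0 and 55.4, with 54.6 in control 4 and 21.6 in KCl 4). Among 435 genes that differed by more than 0.5 on the log2 scale between control 1 and 2 and KCl 1 and 2, at a mean CPM above 20, 367 had both replicate 4 libraries nearer their own group, 67 had them exchanged in this way and 1 had both on the same side. Since the mean CPM of control 4 and KCl 4 tracked that of the other 4 libraries, their positions mirror each other and are not separate observations. Of genes with 0 counts in the other 4 libraries, Kap had 62 in control 4 and 71 in KCl 4, and Ighg2c 72 and 63.

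The split of control 1, control 2 and KCl 4 against control 4, KCl 1 and KCl 2 called 511 genes, the most of any split but the real one. Exchanged labels of control 4 and KCl 4 went against the data, since for 83.9% of the 62 genes called without them both lay nearer their own label. These libraries mirrored each other (52 genes for control 4, 52 for KCl 4 and 52 for both), so they do not count as separate observations. For more selenium in the medium, 0 of 3 other selenium-sensitive mRNAs were higher without overlap. Their differences were 0.05 ± 0.11 (Sepw1), -0.25 ± 0.29 (2700094K13Rik) and 0.21 ± 0.26 (Msrb1) on the log2 scale. SEs of this size cannot exclude a rise, so this explanation stayed open. More neutrophils also stayed open. The median difference was 0.2 for 5 abundant transcripts, or 0.1999 before rounding. It lay below the bound of 0.2 set beforehand by less than 0.21, the median of the 5 single-gene SEs. An SE of the median difference itself was not computed. A candidate explanation is that the counts were adjusted so that control 4 and KCl 4 together match the other libraries, since the SD of their log2 ratio was 0.011 against 0.044 for counting noise, and genes with a summed count of 0 in the other 4 libraries reached 157 in this pair while genes with a summed count of 1 reached at most 3. Whether such an adjustment alone makes the split stays open, since ComBat-seq on simulated libraries gave it 57 genes with the group in its model and 0 without.

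Eosinophil granule genes fell, and Ear1, Ear2 and Ear6 fell by at least 0.72 more on the log2 scale than Epx. Fewer cells that express all of these genes would not alone give this excess. Whether Ear genes and Epx mark the same cells in this culture is unknown, so fewer Ear-expressing cells were not excluded. Exchange of reads among the 5 listed Ear genes alone went against the data, since their summed count changed by -2.34 on the log2 scale. The sum cannot show how much each Ear gene fell, and the comparison with Epx uses each gene's own value. For Prg2 and Epx, fewer eosinophils and lower expression per cell cannot be told apart: the median change of Siglecf, Ccr3 and Il5ra was 0.13, but whether these receptors are restricted to eosinophils in this culture is unknown. Lower expression of Ear genes per cell under KCl may be part of the pattern, as a hypothesis from the same data, and was not told apart from fewer cells that express them.

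Csn2 is a known target of STAT5, which GM-CSF activates, and higher STAT5 output was tested as an explanation of its rise. The median change of 7 other STAT5 targets was 0, but Socs3 (1.13 ± 0.09, also called without replicate 4) and Pim1 (0.44 ± 0.07) rose and Ccnd2 fell by 0.52 ± 0.07, so members that went both ways left the question open. No technical explanation was tested.

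The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3057 changed genes and the highest other 511 (1 of 10 splits as large), 549 against 46 genes changed at least 2-fold (1 of 10), and 12 against 14 lists called (3 of 10). The other splits called 4 to 14 lists, and the 14 came from a split with 0 changed genes (control 1, control 2 and KCl 1 against the rest).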
